A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

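Nucleosomes of 4 Saccharomyces cerevisiae strains, each untreated and treated with 1,10-phenanthroline, were profiled by MNase-seq in 8 libraries. Per the labels, the nuclease digestion was done on semi-intact cells and tuned for each sample to about 80% mononucleosomes, and the libraries were sequenced as pairs of 75 bp reads. The nucleosome calls were made by the authors with nucleR, per the file columns, on the build sacCer3, per the submitters' processing notes. Coordinates on unmodified sacCer3 would hold no steps of the insert length such as those described below. The nucleR version, the aligner, the read filters and the calling threshold are not given in the sources used here. Each library was called separately. The deposited score of a call is the mean of a width score, which falls as fragments at that place scatter, and a height score, which follows coverage. The score is relative within a library, between 0 and 1. The authors' class W (well positioned) held only calls with a width score of at least 0.6 and a height score of at least 0.4. This was tested on all calls not classed as uncertain, with 0 calls off the rule. The deposited start and end coordinates mostly span 147 bp, and the centre of a call was taken as its dyad. The labels give about 10 M read pairs per sample, and the depth of single libraries is unknown, so no counting interval could be given.

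Samples were grouped by the treatment label, and the strain number in the labels served as the replicate. Gene coordinates came from a RefSeq table of assembly R64, the assembly behind sacCer3, with 6002 nuclear protein-coding genes. They span the coding sequence, so a gene start here is the start of the coding sequence and not the transcription start. The strand was read from the systematic name.

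Coordinate offsets between libraries were measured from the calls alone. For each pair of libraries of 1 group, the offset was the shift within 260 bp that put most dyads within 10 bp of a dyad of the other library, in windows of 20000 bp before and after each insertion site. A library held a step where the offset changed by the insert length within 10 bp against each other library of its group. In windows of the same size upstream of every site, or on chromosomes without a site, 0 of 5520 comparisons were off by over 40 bp, and at or beyond the first site of a chromosome 756 of 1524 were. Regions from 1000 bp before the first site to the end of chromosomes IV, VII, VIII, XV and XVI were therefore left out of all consensus, gene and position results, which kept 4728 genes. This departs from the design fixed before the data were examined, and the same results with the offset subtracted are among the alternatives.

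Dyads of all 8 libraries were pooled without using the treatment and smoothed with a Gaussian kernel of SD 20 bp. Maxima at least 80 bp apart made the consensus nucleosomes, and each call was assigned to the nearest one within 60 bp. Those called in at least 4 libraries formed the gene arrays. The -1 and +1 nucleosomes were the pair with the widest gap whose downstream member lay from 150 bp upstream to 200 bp downstream of the gene start. Spacing was the median distance between neighbouring dyads inside 1 gene, from 100 to 300 bp. Phased genes had at least 4 nucleosomes and a distance from +1 to last within 41 bp of a multiple of a repeat length 5 bp above the 160 bp tried as an alternative. The gene-body score was the mean score of calls inside a gene with at least 3 calls in every library. For the inserted genes, calls within 150 bp of the site were left out, since fragments with inserted sequence need not be placed on the reference.

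Library measures were compared with the exact two-sided permutation test on the difference of means over the 70 splits of 4 against 4, with Benjamini-Hochberg adjustment over 8 measures. Scores, dyads, gene-body scores, widths of the depleted region and +1 positions were compared with limma 3.58.1 in R 4.3.3 without a block, with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists were tested with camera at its preset correlation of 0.01, camera with an estimated correlation and fry. The inserted genes were tested by the 24 assignments of the 4 pairs of genes to the 4 strain labels. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 did the remaining steps, and matplotlib 3.10.9 drew the figures. The per-gene comparisons of width and +1 position, the lists tested on them, the distance from +1 to last and the place of gained and lost nucleosomes were added after seeing the data.

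The genes named were set by a rule: the 10 largest rises and 10 largest falls in gene-body score past the threshold with all 4 strain labels moving the same way, the 2 members of each of 15 lists with the smallest p in the direction of the list, the 8 inserted genes and the 5 genes of the genotype. Other genes are named where a count of 5 or fewer called them or where the text says they were chosen after their values were seen, and all called ribosomal protein genes are named. The rule, the lists, the tests and most alternatives were fixed before the data were examined.

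The untreated and treated library of 1 strain number come from the same strain, so the numbers pair the samples. The deviations of the 2 libraries from their group means correlated at 0.0385 to 0.302 across consensus nucleosomes, 0.0836 to 0.344 across gene-body scores and 0.0147 to 0.241 across dyads for the 4 same-numbered pairs. For differently numbered pairs the values ran from -0.221 to 0.170. The strain number as a block is given beside a result where it changed the call.

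The limma and camera steps were tested on simulated data made from the real means and spreads, with each gene or nucleosome drawn independently. The position measures were tested on copies of 1 real library, with closely spaced calls removed and a small random shift added. Among 4006 genes limma recovered 2, 29, 41 and 46 of 50 genes with simulated differences of 0.05, 0.1, 0.15 and 0.2 and called 7 unchanged ones. Among 47441 nucleosomes it recovered 0, 0, 1 and 11 of 50 simulated score differences of the same sizes, and 0, 18, 29 and 35 of 50 simulated dyad shifts of 10, 20, 30 and 40 bp. Among 4131 genes it recovered 10, 29, 34 and 43 of 50 widths changed by 10, 20, 30 and 40 bp. In those copies a simulated +1 shift of 4.89 bp came back as 4.84 bp, and 100 of 100 removed nucleosomes were recovered as lost. In the real libraries 37.9% of untreated and 47.1% of treated calls overlapped the next, so recovery there may be lower. In the simulated lists of 90 genes, which held no correlation between genes, camera called the raised one and not the unchanged one.

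The alternatives tried were calls with a score of at least 0.4, assignment within 30 bp, scores centred on the library median, the median over calls, at least 6 calls, each score component alone, other distance limits and repeats, another +1 rule, the strain block and each strain label left out in turn. Added after seeing the data were the offset-removed coordinates, other minimum support, well-positioned or non-overlapping neighbours for the spacing, the library with the step as the carrier (alone, under phenanthroline and with calls of score at least 0.4), and the block and left-out strain labels for the counts of widths and +1 positions.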

Results

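Nucleosome positions were measured by micrococcal nuclease sequencing (MNase-seq), in which the nuclease digests the DNA between nucleosomes and the protected fragments are sequenced, in 4 strains of the budding yeast Saccharomyces cerevisiae. Each strain was labelled as carrying an inserted sequence of 81 bp in 2 genes. Each strain gave 1 untreated library and 1 library from cells treated with 1,10-phenanthroline, a metal chelator used to block transcription in yeast, at 100 µg/ml for 30 min at 30 °C. The cells were synchronised in G1. The series was designed to ask how a change of gene length, and how transcription, alter the periodic arrangement of nucleosomes along genes. The deposited values were nucleosome calls, each with a centre (dyad), a score from 0 to 1 and a class. The 8 libraries held between 72650 and 75086 calls. The sequencing depth behind each library is unknown from these calls, and the labels give about 10 M read pairs for every sample alike. The treatments were compared with the 4 strains as replicates (n = 4 per group). The labels name a different strain for each library of a group, so the p-values measure the spread between libraries of different strains. No strain was repeated within a treatment. The labels do not say whether the untreated and treated library of 1 strain came from separate cultures.

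The genes named in the genotype were examined first, as a check of the labels. MET17 (the gene labelled MET15, methionine synthesis) and URA3 (uracil synthesis) held 0 calls in all 8 libraries. HIS3 (chromosome XV, 721946 to 722608), also given as deleted, held 2 to 3 calls. LEU2 (III, 91324 to 92418), which the labels give both as deleted and as the marker placed in BAR1, held 8 to 11 calls. BAR1 (IX, 322342 to 324105), the protease that degrades alpha factor, held 11 to 13 calls in the 8 libraries. A marker placed in a gene can leave the sequence of that gene in the genome, so these calls do not test the label of a disrupted BAR1.

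The insertion sites were examined next. At each of the 8 sites the offset of the call coordinates of 1 strain label against the other libraries rose by about the length of the insert, and this strain label was never the one named for the gene. Offsets from earlier sites of the same chromosome remained, so only the step is given. Of 64 pairs of a library and a site, 16 held such a step, with a median of 81 bp, and 0 of the 16 were in the library of the labelled strain. The step at CKB2 and DGK1 was in both libraries labelled strain 2, that at PPT1 and SLM3 in both labelled strain 3, that at TRP4 and PAN5 in both labelled strain 4 and that at UBX5 and BSP1 in both labelled strain 1. The 16 steps measured 77.5 to 84 bp, and the largest in the remaining pairs was 6.5 bp. For this reason each sample is called here the library labelled strain 1, 2, 3 or 4, and every direction drawn from the insertions rests on those labels. The untreated and treated libraries of 1 number held their steps at the same genes, so the treatment comparison was made as labelled, in the regions that lie upstream of every site.

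**Figure D1:**
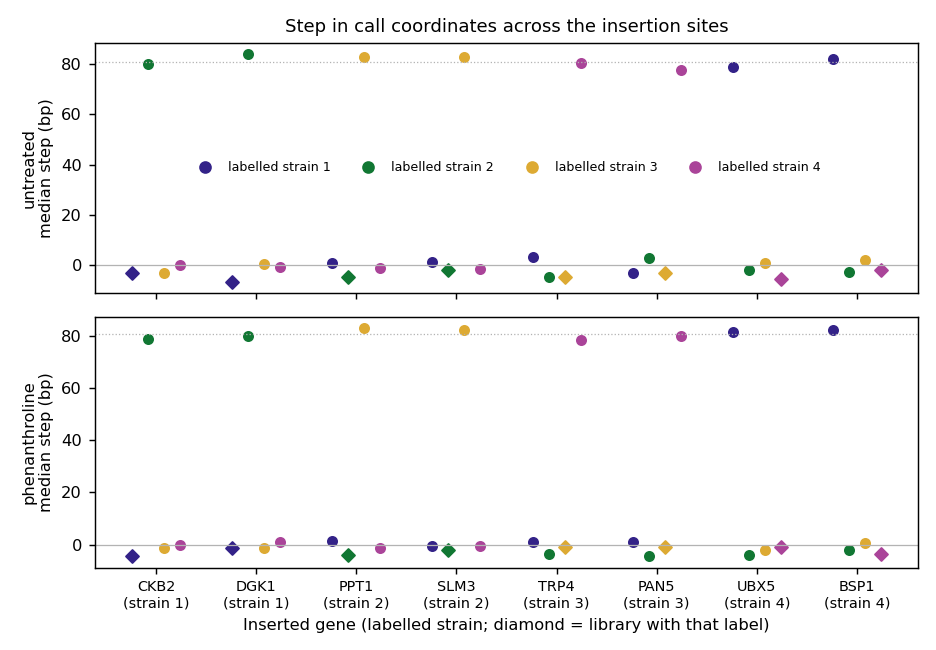
Median step in call coordinates (bp) from the 20000 bp before to the 20000 bp after each of the 8 insertion sites, for the 4 untreated (top) and 4 phenanthroline libraries (bottom), coloured by strain label, with a diamond for the library whose label names the gene. At every site the labelled library sits near 0 and the library of 1 other label sits between 77.5 and 84 bp.

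Phenanthroline was accompanied by more nucleosome calls, fewer of them well positioned, wider nucleosome-depleted regions at gene starts and a first nucleosome (+1) that lay farther into the gene. The number of calls was 73025.5 ± 350.7 in untreated and 74717.2 ± 271.0 in treated libraries (SD, n = 4 each), a difference of 1691.8, or 821 among calls of score 0.4 or more (exact p = 0.0286). Well-positioned calls made up 55.1% ± 1.80 of calls without and 49.5% ± 1.73 with phenanthroline. The mean call score was 0.659 ± 0.00564 and 0.645 ± 0.00259. The depleted region, measured between the dyads of the -1 and +1 nucleosomes, had a median width of 257 ± 4.24 bp in untreated and 267.25 ± 1.26 bp in treated libraries. The +1 dyad lay on average at -10.5 ± 2.27 bp from the annotated start of the coding sequence in untreated and at -6.20 ± 0.792 bp in treated libraries. The median distance between neighbouring dyads in genes was 162.25 ± 0.957 bp and 158 ± 0 bp, a difference of -4.25 bp. It was -2.5 bp with a narrower range of distances, -2.62 bp with calls of score 0.4 or more and -4.11 bp as a mean distance (exact p = 0.0286 each).

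In each of these 6 measures, and in the score difference between phased and antiphased genes given further on, the treated and untreated libraries did not overlap. All 7 gave an exact two-sided permutation p of 0.0286, the smallest that 4 libraries against 4 allow, an adjusted p of 0.0327 over 8 library measures, and the same direction in 4 of 4 strain labels. The gap was small at the +1, with -7.37 bp in the untreated library labelled strain 3 and -7.36 bp in the treated one labelled strain 2. Within strain label 3 the +1 changed by 1.34 bp and the depleted region by 4 bp. With the strain label as a block the exact sign-flip test gave p = 0.125 for each of the 7, the smallest value it allows with 4 pairs. The 7 measures are not separate evidence. The depleted region is measured from the same +1 dyad, and more calls on the same genome lie closer together on average. Calls that overlapped the next call rose from 37.9% ± 1.06 to 47.1% ± 0.364 (SD, n = 4, exact p = 0.0286, adjusted p = 0.0429 over 6 further measures, 0.125 with the strain block). Among calls that overlap no other call, 49.2% of untreated and 37.6% of treated calls, the dyad distance was 165.5 ± 1 bp and 164.25 ± 0.5 bp (n = 4, exact p = 0.143). No distance shorter than a call can enter that comparison. With the call nearest the gene start taken as +1, its shift was 4.01 bp (exact p = 0.0571).

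**Figure D2:**
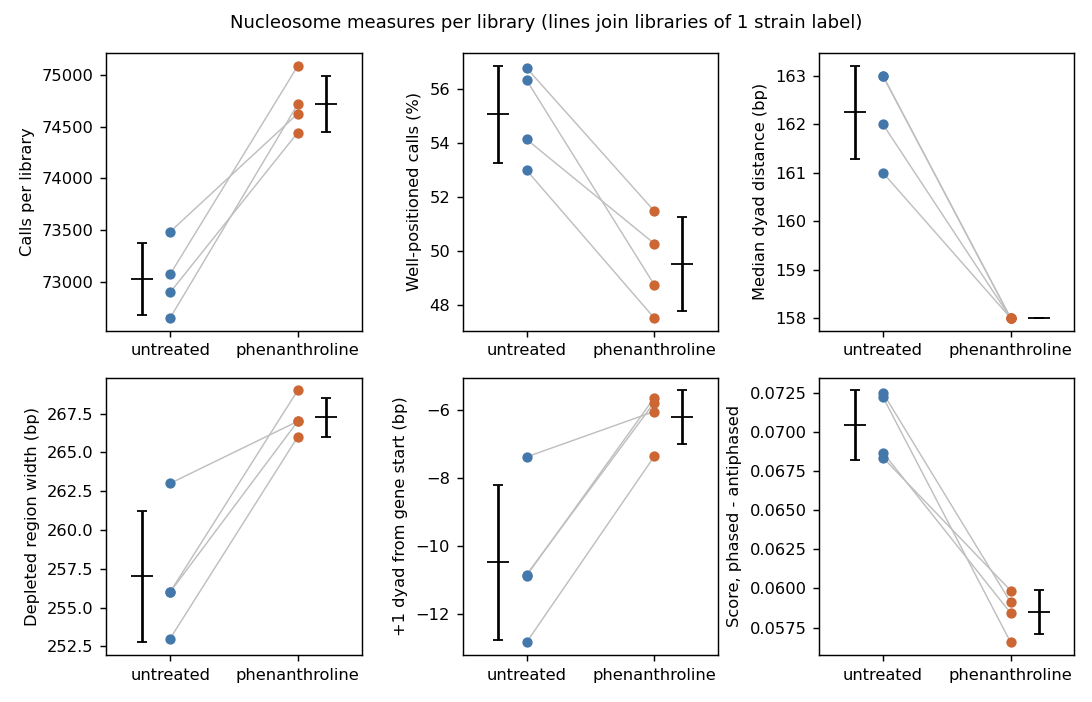
Number of calls, share of well-positioned calls (%), median dyad distance (bp), depleted region width (bp), +1 position (bp from the gene start) and score of phased minus antiphased genes, 1 point per library, with the mean and SD of 4 beside each group and lines between libraries of 1 strain label. In all 6 panels the 4 lines run in the same direction. The vertical axes do not start at 0.

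Along the gene the shift of the dyads changed sign. The nucleosome upstream of the depleted region (-1) lay 3.72 bp farther from the gene under phenanthroline (difference -3.72 bp over 4246 nucleosomes), the +1 lay 4.33 bp farther downstream (4389 nucleosomes), and the last nucleosome of a gene lay nearer to the gene start (difference -7.05 bp, 2549 nucleosomes). Each of the 3 moved the same way in 4 of 4 strain labels with an exact p of 0.0286, and none passed after adjustment over the 8 positions (adjusted p = 0.0762). The differences at +2, +3 and +4 were 1.79, 0.402 and -1.41 bp (exact p = 0.371, 0.8 and 0.457), and those at +5 and +6 were -3.61 and -5.33 bp (exact p = 0.114 each). Within strain labels, +5 ran from -4.40 to -2.06 bp and +6 from -6.62 to -3.96 bp, negative in 4 of 4. By exact sign flips on the pairs both had p = 0.125, the smallest that 4 pairs allow. Averaged over +2 to +6 the shift was -1.63 bp (exact p = 0.429, adjusted p = 0.429). In 2477 genes whose +1 and last nucleosome were called in all libraries, the distance from +1 to last was 1922.6 ± 4.56 bp in untreated and 1910.9 ± 0.788 bp in treated libraries (SD, n = 4). This difference of -11.7 bp was a measure added after the shifts had been seen. It rests on the same +1 and last dyads, so it is not separate evidence from their shifts. Its exact p, not adjusted, was 0.0286 (0.125 with the strain block), with the same direction in 4 of 4 strain labels. The distance divided by the number of intervals in each gene, averaged over genes, was 155.6 ± 0.441 and 154.4 ± 0.0807 bp (n = 4, exact p = 0.0286).

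**Figure D3:**
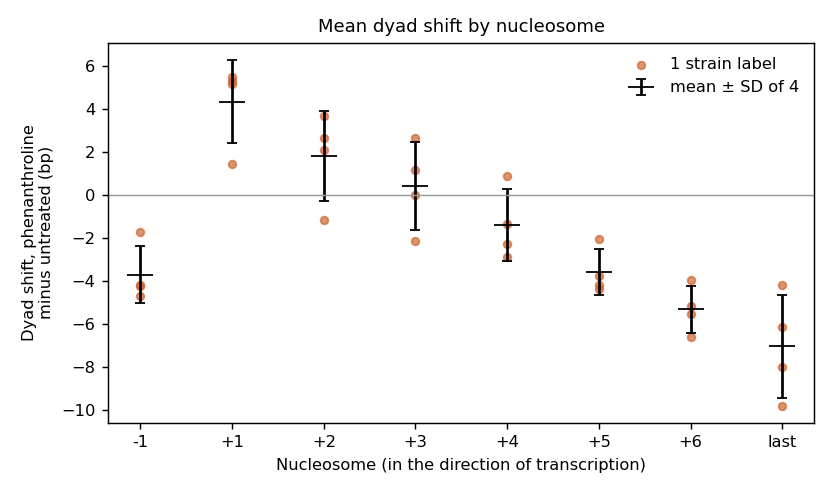
Mean dyad shift (phenanthroline minus untreated, bp, positive in the direction of transcription) of the -1, +1 to +6 and last nucleosome of genes. Points are the 4 strain labels and bars their mean and SD, and the means run from 4.33 bp at +1 to -7.05 bp at the last nucleosome.

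Single promoters were compared with limma in 4131 genes. The depleted region was wider in 1034 and narrower in 78 genes, and the +1 nucleosome had moved downstream in 769 and upstream in 76 genes. The following genes were chosen after their values were seen, from the top of each list. The depleted region of SEC15, an exocyst subunit, widened from 254.25 ± 4.5 to 302.25 ± 2.99 bp (SD, n = 4, limma adjusted p = 0.000749, 0.0197 with the strain block). The region shared by the divergent genes ADE1 (purine synthesis) and BUD14 widened from 305.25 ± 6.13 to 356.25 ± 3.30 bp (limma adjusted p = 0.000749), and the +1 of ADE1 lay 52.5 bp farther downstream. That of BDF1, a bromodomain protein of the general transcription machinery, narrowed from 547.75 ± 5.74 to 521.25 ± 3.30 bp (limma adjusted p = 0.00777), and its +1 lay 25 bp farther upstream (SE 2.04, limma adjusted p = 0.00307, 0.0512 with the strain block). The counts rested on single strain labels: without strain 1, 2 or 4 they were 17, 127 and 25 genes for the width and 7, 96 and 18 for the +1. Without strain 3 they were 1341 and 1066. With the strain block they were 65 and 8, and 1693 and 1592 genes had a limma unadjusted p below 0.05. Without the block 1836 and 1666 genes did.

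Of the gene groups fixed before the data were examined, 3 were called for this width with camera's preset correlation, and none of the 3 held with an estimated correlation. Genes of the mitochondrial ribosome had wider depleted regions in 19 of 41 members and narrower ones in 0, or 23 and 0 adjusted over the list alone (median difference 9.75 bp, 7.25 bp over all genes, camera adjusted p = 0.00363, 0.616 with an estimated correlation). Chaperone genes had narrower ones in 4 of 17 members and wider ones in 0, also adjusted over the list alone (median -0.75 bp, camera adjusted p = 0.000314, 0.0562 with an estimated correlation). Genes of glycolysis and fermentation had 1 narrower and 0 wider of 9 members, also adjusted over the list alone (median 1.12 bp, camera adjusted p = 0.0213, 0.187 with an estimated correlation, 0.0845 without the libraries labelled strain 3). The other 12 lists were not called, and with the strain block the G2/M genes were (camera adjusted p = 0.0929 without and 0.0477 with it, 0.283 with an estimated correlation and 0.0321 without the libraries labelled strain 2).

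Periodicity within genes was compared between phased genes, whose distance from +1 to last nucleosome lies within 41 bp of a whole multiple of a fixed repeat length (2303 genes), and the 1578 antiphased genes. Nucleosomes between +1 and last scored higher in phased genes, and this difference was smaller under phenanthroline: 0.0704 ± 0.00222 in untreated and 0.0585 ± 0.00141 in treated libraries (SD, n = 4, exact p = 0.0286, adjusted p = 0.0327). The mean score of phased genes was 0.729 ± 0.00788 and 0.725 ± 0.00466 (n = 4, exact p = 0.429), and that of antiphased genes 0.658 ± 0.00579 and 0.667 ± 0.00595 (n = 4, exact p = 0.114). With the repeat length set 5 bp shorter, at 160 bp, the change of the difference was 0.00269 (exact p = 0.629).

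A consensus map of 57416 nucleosomes was made from all 8 libraries, of which 47441 were called in every library. limma found a changed score at 4067 of these, with 1376 higher and 2691 lower under phenanthroline. On scores centred on the library median the split was 2200 higher and 1719 lower. The dyad had shifted at 544, with 282 shifted to higher and 262 to lower coordinates, and at 1043 with calls assigned within 30 bp. Without the libraries labelled strain 1, 3 or 4 the count of changed scores was 525, 2096 and 1183, and without those labelled strain 1 or 4 the count of shifted dyads was 0 (limma, 6001 at an unadjusted p below 0.05) and 123. With the strain block limma called 0 shifted dyads, with 10601 at an unadjusted p below 0.05.

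Nucleosomes called in all 4 libraries of 1 treatment and in none of the other numbered 70 gained and 83 lost under phenanthroline, 153 together and 304 among calls with a score of at least 0.4. These were calls of low score, 0.365 on average for gained, 0.407 for lost and 0.675 for all consensus nucleosomes. Of the gained ones 46 lay inside genes, 3 within 400 bp upstream of a gene and 21 elsewhere. Of the lost ones 18 lay inside genes, 27 upstream and 38 elsewhere. Lost nucleosomes lay upstream of genes more often than gained ones (odds ratio 10.8, Fisher's exact test p = 8.27e-06, a test chosen after the counts were seen). The test counts nucleosomes as units, not libraries. Over all consensus nucleosomes 77.5% lay inside genes, 10.9% upstream and 11.6% elsewhere. For gained ones these shares were 65.7%, 4.29% and 30%, and for lost ones 21.7%, 32.5% and 45.8%. The highest-scoring lost ones upstream, named after their values were seen, stood before MIT1 (dyad at V 141614), a regulator of pseudohyphal growth, YIL055C (IX 254097), SPO24 (XVI 645887), OCA1 (XIV 439543) and DBR1 (XI 169099), the RNA lariat debranching enzyme. The highest-scoring gained ones lay inside FLO10 (XI 648337), a cell wall flocculin, MEH1 (XI 451648), RKR1 (XIII 765178) and URB2 (X 510696).

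The score of nucleosomes over the gene body was compared in 4006 genes with limma. It rose in 131 genes and fell in 164. On centred scores it rose in 416 and fell in 87, and with the height component alone 595 genes changed. The largest rises were in RCR1 (II, 245906 to 246547), from 0.489 ± 0.0481 to 0.725 ± 0.0541 (SD, n = 4, limma adjusted p = 0.00425), YKL154W, which encodes the membrane subunit of the signal recognition particle receptor (difference 0.211, SE 0.0493, limma adjusted p = 0.0305), and DSK2 (XIII, 818827 to 819948), a ubiquitin receptor (difference 0.205, SE 0.0159, limma adjusted p = 0.000301). RPS1B (0.192) and RPS4A (0.154), proteins of the small ribosomal subunit, UMP1 (0.183), a proteasome assembly factor, SSO1 (0.170), a t-SNARE of the plasma membrane, POP3 (0.163), a subunit of RNase P, MAY24 (0.154) and PAC10 (0.148), a prefoldin subunit, completed the 10 largest rises. RPS1B and RPS4A each have a near-identical second copy whose reads may not be told apart, so their values are uncertain.

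The largest falls were in DOM34 (XIV, 627456 to 628616), a factor of no-go mRNA decay, from 0.725 ± 0.0725 to 0.516 ± 0.0442 (SD, n = 4, limma adjusted p = 0.0112), and RGI1 (V, 292066 to 292551), a gene of respiratory growth, from 0.885 ± 0.0245 to 0.684 ± 0.0385 (limma adjusted p = 0.00258). YKL063C (difference -0.193), UIP4 (-0.185), RNP1 (XII, 46714 to 47463; -0.178, SE 0.0166, limma adjusted p = 0.000961), ADE1 (-0.176), HMRA1 (-0.173), IES5 (-0.160), a subunit of the INO80 chromatin remodeller, DFP3 (-0.158) and RRF1 (-0.156), the mitochondrial ribosome recycling factor, followed. HMRA1 shares its sequence with the expressed mating-type locus, so its value is uncertain. The 20 genes moved the same way in 4 of 4 strain labels by the rule that chose them. Their order depended on the calls used. With calls of score 0.4 or more the difference was 0.162 in RCR1, 0.0746 in YKL154W, -0.108 in DOM34, -0.116 in RGI1 and -0.0529 in RNP1, against 0.187 in RPS1B and -0.158 in UIP4. With the width component alone SSO1, UMP1, POP3, PAC10, YKL063C and RRF1 were not called, and with the median over calls RNP1, IES5 and DFP3 were not (limma adjusted p = 0.0842, 0.0552 and 0.0824). Without the libraries labelled strain 1 limma called 3 genes, DSK2, RNP1 and RGI1. Without those labelled strain 3 or 4 it called 139 and 56 genes.

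Of 15 gene lists fixed before the data were examined, ribosomal protein genes had the smallest adjusted p with camera's preset correlation. Their gene-body score averaged 0.635 in untreated and 0.662 in treated libraries, against 0.692 and 0.686 over all genes. Of 92 measured members 60 had a positive difference, 9 rose and 1 fell (13 and 1 adjusted over the list alone), with a median of 0.0246 and a camera adjusted p of 0.000195. With an estimated correlation the camera adjusted p was 0.206, and with the height component of the score alone 0.442. Besides RPS1B and RPS4A the members that rose were RPL25 (0.124), RPS16B (0.144), RPL17A (0.122), RPL21A (0.102), RPL23B (0.0975), RPL2B (0.0898) and RPL19B (0.0807), and RPL35B fell by 0.0893. RPL25 was not called with calls of score 0.4 or more or with the height component alone (limma adjusted p = 0.0525 and 0.0606). Most of these have a second copy.

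Genes of glycolysis and fermentation had a positive difference in 11 of 12 measured members with a median of 0.0321 (camera adjusted p = 0.0458, 0.314 with an estimated correlation), and limma called 0 members, also when adjusted over the list alone, with 5 at an unadjusted p below 0.05. The smallest p values were those of FBA1, the aldolase (difference 0.0745, SE 0.0234, limma adjusted p = 0.0783), and CDC19, the pyruvate kinase (0.0740, SE 0.0247, limma adjusted p = 0.0923). Both were called on centred scores (limma adjusted p = 0.0216 and 0.0308) and with the height component alone (0.0315 and 0.0404), and CDC19 with the median over calls (0.0329). The camera adjusted p for this list was 0.163 with calls of score 0.4 or more, 0.0716 on centred scores, 0.179 without the libraries labelled strain 1 and 0.1504 without those labelled strain 2. CDC19 had a difference of -0.00210 in the width component alone. Meiosis and sporulation genes, which include the recombination protein SPO11 (-0.0543, limma adjusted p = 0.0963) and the septin SPR3 (-0.0747, limma adjusted p = 0.108, 0.0130 with the height component alone), had 14 negative differences in 16 members and a median of -0.0266, with 0 members called by limma over all genes or adjusted over the list alone and 3 at an unadjusted p below 0.05. Their camera adjusted p was 0.167, and with calls of score 0.4 or more it was 0.00938, a call in the downward direction, while fry, which asks whether the genes move one way and makes no comparison with other genes, gave an adjusted p of 0.00125.

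The other 12 lists had no camera call (adjusted p of 0.682 or above), but some members passed the limma test in both directions. In the zinc regulon, the genes of the response to low zinc, 2 of 16 genes rose, ADH4 (0.135) and ZPS1 (0.107), and 2 fell, the vacuolar zinc transporter ZRT3 (-0.127) and the peroxiredoxin TSA1 (-0.0863), with 2 and 3 adjusted over the list alone. Among 18 general stress genes 1 rose, the hydrophilin GRE1 (0.124), and 2 fell, the trehalose synthase TPS1 (-0.134) and the hexokinase HXK1 (-0.0663), and 2 and 2 did adjusted over the list alone. Of 19 chaperone genes SSA2 rose (0.0840, its near-identical copy SSA1 makes this uncertain) and HSP26 fell (-0.152), with 2 and 1 adjusted over the list alone, and YDJ1 stood at 0.0771 (limma adjusted p = 0.0510). Of 23 pheromone response genes the kinase FUS3 (0.119) and the phosphatase MSG5 (0.105) rose and the receptor STE2 fell (-0.0650), with 3 and 2 adjusted over the list alone. Of 67 ribosome biogenesis genes NOG2 rose (0.0871) and NOP16 (-0.0923) and MPP10 (-0.0882) fell, with 1 and 1 adjusted over the list alone, and SQT1 stood at 0.0525 (limma adjusted p = 0.0864). Of 30 genes of the mitochondrial ribosome MRPL15 (-0.0806) and RSM7 (-0.0890) fell and 0 rose, the same number as adjusted over the list alone. Several of these calls depended on the setting. With calls of score 0.4 or more the difference of TSA1 was 0.0542 (limma adjusted p = 0.136), and ZRT3, HXK1, SSA2 and RSM7 were not called (limma adjusted p = 0.270, 0.0994, 0.106 and 0.313). On centred scores TSA1, HXK1 and MRPL15 were not called (limma adjusted p = 0.0976, 0.128 and 0.0508), while YDJ1 and SQT1 were (0.0211 and 0.0216). YDJ1 and SQT1 were also called with the height component alone (0.00664 and 0.0145), and YDJ1 with the median over calls (0.0252) and at least 6 calls (0.0470). With the median over calls ZRT3, TPS1, MRPL15 and RSM7 were not called, and with the width component alone TSA1, HXK1, SSA2, FUS3, MSG5 and NOG2 were not.

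In the remaining 6 lists limma called 0 genes, over all genes or adjusted over the list alone. At an unadjusted p below 0.05 there were 3 of 22 G1/S genes, 1 of 19 iron regulon genes, 1 of 15 glucose-repressed genes and 0 of the 11 G2/M, 6 translation elongation and 2 core histone genes measured. Their members with the smallest p in the direction of the list were MRS4 (-0.138, limma adjusted p = 0.110, 0.0491 with the strain block) and VHT1 (-0.0375) in the iron regulon, TOS4 (-0.0768) and PCL1 (-0.126) among G1/S genes, KIN3 (0.0341) and CLB1 (0.0224) among G2/M genes, ICL1 (0.0587) and FBP1 (0.0301) among glucose-repressed genes, TEF4 (0.0226) and CAM1 (0.0128) in translation elongation and HTB2 (-0.0431) and HTA2 (-0.0206) among core histones. In other settings limma called MRS4 with the median over calls (adjusted p = 0.0484) and without the libraries labelled strain 3 (0.0302), ICL1 with the height component alone (0.0268), and TOS4 and PCL1 without those labelled strain 2 (0.0228 and 0.0270). HTA2 stood at 0.00350 on centred scores. The sign of the list differed between its median and the camera test in 3 lists: glucose-repressed genes (median -0.0106), chaperones (median -0.0118) and pheromone response (median -0.00265) all ranked upward. Ribosome biogenesis had a mean of -0.00343, a median of 0.000946 and an upward camera direction.

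**Figure D4:**
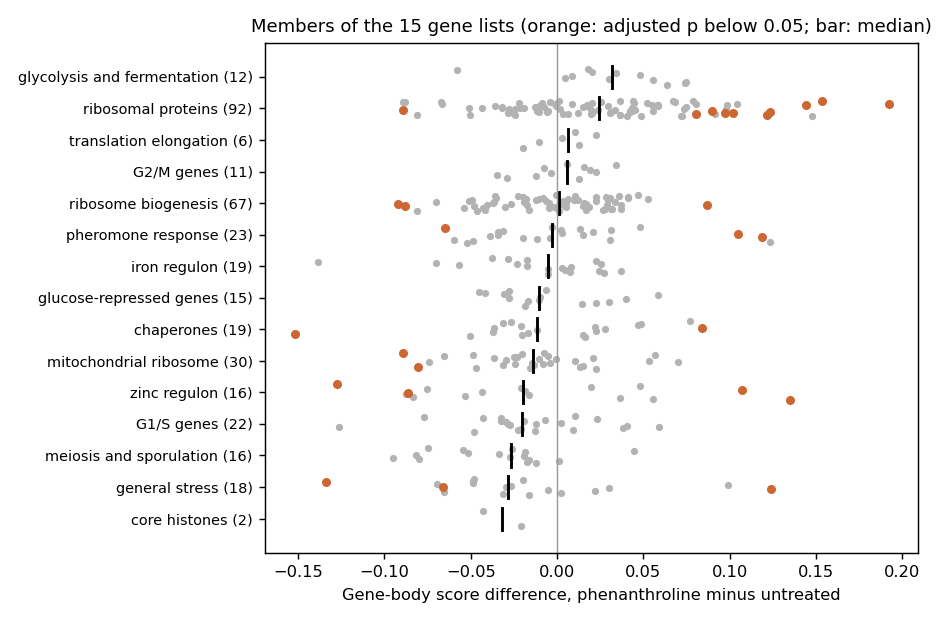
Difference in gene-body score (phenanthroline minus untreated) of every measured member of the 15 lists, with the number measured in parentheses, the list median as a bar and members past a limma adjusted p of 0.05 in orange. Medians run from 0.0321 for glycolysis and fermentation to a negative value for core histones, which have 2 measured members.

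The inserted genes were compared between the labelled carrier and the other 3 strain labels, to ask whether a longer gene changes the arrangement of its nucleosomes. Their coding sequences (build sacCer3) are CKB2 (XV, 405768 to 406544, site at 406248), DGK1 (XV, 899056 to 899928, site at 899667), PPT1 (VII, 736662 to 738203, site at 737615), SLM3 (IV, 392659 to 393912, site at 393462), TRP4 (IV, 1184747 to 1185889, site at 1185196), PAN5 (VIII, 224030 to 225169, site at 224581), UBX5 (IV, 1127872 to 1129374, site at 1128586) and BSP1 (XVI, 883828 to 885558, site at 884578). CKB2 encodes a subunit of casein kinase 2, DGK1 a diacylglycerol kinase, PPT1 a protein phosphatase and TRP4 an enzyme of tryptophan synthesis. With 81 bp added, the distance from +1 to last nucleosome would move 6 of them from phased to antiphased and DGK1 and BSP1 from antiphased to phased. This holds for the repeat length used to define phased genes.

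Over the 8 genes no difference between the labelled carrier and the other libraries passed the test. In untreated libraries the mean score of calls at least 150 bp from the site was 0.787 in the carrier and 0.735 in the others, a difference of 0.0520 with 7 of 8 genes higher (exact p = 0.0833 over 24 assignments). The share of well-positioned calls was 87.9% and 75.2% (difference 12.7 points, exact p = 0.125), the dyad displacement 9.08 and 12.03 bp (difference -2.95 bp, exact p = 0.125, and 1.55 bp with calls of score 0.4 or more, exact p = 0.667) and the distance from the site to the nearest dyad 56.5 and 49.1 bp (exact p = 0.708). Under phenanthroline the differences were 0.0106 in score (exact p = 0.458), 0.678 points (exact p = 0.875), -1.40 bp (exact p = 0.417) and 10.7 bp (exact p = 0.583). The smallest p that the 24 assignments allow is 0.0417. With all calls in the gene, those near the site included, the untreated score was 0.785 in the carrier and 0.731 in the others, a difference of 0.0540 with 6 of 8 genes higher (exact p = 0.0833). On this measure, among 2955 genes of 700 to 1900 bp in the same libraries, the carrier difference of CKB2 (0.116) stood at the 99.3 percentile, that of PPT1 (0.117) at 98.5, TRP4 (0.107) at 98.0, UBX5 (0.0674) at 93.9, SLM3 (0.0547) at 87.3, PAN5 (0.0135) at 65.4, DGK1 (-0.0120) at 30.0 and BSP1 (-0.0305) at 16.3. All of these values take the carrier from the labels, while the coordinate steps lay under another strain label at all 8 sites. In the stepped untreated libraries CKB2 (-0.278), TRP4 (-0.201) and UBX5 (-0.165) stood at percentile 0 on the same measure. PPT1 (-0.130) stood at 1.29, SLM3 (-0.0613) at 13.2 and BSP1 (0.0203) at 67.3. PAN5 (0.149) stood at 99.86 and DGK1 (0.240) at 99.97. With the library that holds the step taken as the carrier, the difference in untreated libraries was -0.0238 in score (exact p = 0.542). It was 5.26 bp in displacement (exact p = 0.0417, and 6.68 bp with calls of score 0.4 or more, exact p = 0.0833). Under phenanthroline the difference was 0.00417 in score (exact p = 0.792) and 1.51 bp in displacement (exact p = 0.25). The nearest dyad, in offset-removed coordinates, lay 17 bp from the site in the stepped and 62.2 bp in the other untreated libraries. It was nearer in 7 of 8 genes. Under phenanthroline it lay 8.5 and 57.9 bp away, nearer in 8 of 8 genes (exact p = 0.0417 each). Removing the offset takes the added sequence out of the stepped library alone. In the stepped untreated libraries the nearest dyad of CKB2, DGK1, PPT1, PAN5 and UBX5 then stood exactly at the site (0 bp). The correction itself can shorten these distances, so the p-values do not show nucleosomes nearer the site.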

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

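The comparison of the stepped libraries at 150 bp from the sites was chosen after the coordinate steps had been seen, and the comparison at 300 bp was chosen before its result was seen.

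Of 63 groups of 4 values, 4 held a library far from the other 3, where chance gives about 1 in 20 groups. The untreated library labelled strain 2 stood apart in the dyad shift at +4 (-4.52 bp, others 1.91 to 3.11 bp), +5 (-3.36 bp, others 3.19 to 3.71 bp) and +6 (-2.63 bp, others 4.20 to 4.84 bp). The treated library labelled strain 2 was not flagged but was also the lowest treated one there. It stood at -3.64 bp at +4 (others -0.370 to 0.957 bp), -5.42 bp at +5 (others -1.21 to -0.0704 bp) and -6.59 bp at +6 (others -2.43 to -0.702 bp). The untreated library labelled strain 1 stood apart in the mean score of the -1 nucleosome (0.828, others 0.813 to 0.815).

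Steps of about 81 bp in the call coordinates, a signal outside the planned comparisons, were present in 16 pairs of a library and an insertion site, each time under a strain number other than the one labelled for that gene. A shift of the strain numbers against the inserted genes is a candidate explanation: calls at least 150 bp from the sites differed in score from the other 3 libraries by 0.122 on average in the stepped libraries, the highest of 24 assignments (highest other 0.111), and by 0.0596 in the labelled ones. Under phenanthroline the value was 0.0733, again the highest of the 24 assignments (highest other 0.0651). The comparison at 300 bp and beyond could not tell this apart from DNA as labelled but placed on the reference sequence of another strain. There the stepped libraries stood at 0.0850 in untreated cells, below the highest other assignment at 0.0872. Under phenanthroline they stood at 0.0625, above the highest other at 0.0590. Both explanations take the stepped libraries to have been placed on a reference that holds the inserts, since unmodified sacCer3 would give no step. A shift of the strain numbers alone would not give one. In untreated libraries the nearest dyad lay 17 bp from the site in the stepped and 62.2 bp in the others. Under phenanthroline it was 8.5 and 57.9 bp (exact p = 0.0417 each over 24 assignments). For the labelled libraries it was 56.5 and 49.1 bp untreated (exact p = 0.708). These distances are in offset-removed coordinates, which take the added sequence out of the stepped library alone and can by themselves shorten its distance. How fragments with inserted sequence were placed is unknown, so the distances do not decide between the explanations. No biological explanation was tested, because the design gives none for a step under another strain number.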

How the results depend on the processing

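The offset-removed coordinates, the other minimum support, the well-positioned and non-overlapping neighbours, the stepped library as carrier (alone, under phenanthroline and with calls of score 0.4 or more), and the block and left-out strain labels for widths, +1 positions and the list block were chosen after the result was seen. The cause of the changes below was not tested, except where fewer samples or genes set them.

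With the strain number as a block, the exact sign-flip test on the pairing gave p = 0.125, the smallest it allows, for the difference in calls (1691.8), well-positioned share (-5.54 points), mean score (-0.0145), spacing (-4.25 bp), depleted region (10.2 bp), +1 (4.29 bp) and phased minus antiphased score (-0.0119). Under the block limma called 0 shifted dyads, 65 widths and 8 +1 positions. The shifts of the -1 and last nucleosome, the distance from +1 to last, the overlapping and uncertain shares and the width and height scores also had p = 0.125 by exact sign flips. The block gave 334 genes and 3085 nucleosome scores, and the 2 list calls on gene-body score held. G2/M genes were called by width (camera adjusted p = 0.0477, 0.283 with an estimated correlation and no block). Among named genes MRS4 passed (-0.138).

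Without 1 strain label, 3 libraries against 3 allow no p below 0.1. The differences then ran from 1567 to 1875 calls, -6.11 to -4.87 points, -0.0159 to -0.0126 in mean score, -4.67 to -4 bp in spacing, 9.08 to 12.7 bp in the depleted region, 3.98 to 5.11 bp at +1 and -0.0136 to -0.0106 in phased minus antiphased score, each in its main direction. The limma counts ran from 3 to 231 genes (3 without strain 1, 139 without 3, 56 without 4), 525 to 2897 nucleosome scores (525, 2096 and 1183 without 1, 3 and 4), 0 to 756 dyads (0 and 123 without 1 and 4), 17 to 1341 widths (17, 127 and 25 without 1, 2 and 4) and 7 to 1066 +1 positions (7, 96 and 18 without 1, 2 and 4). Gained and lost nucleosomes numbered 261 to 409, more than 153 by construction, since fewer libraries must share a call. List calls ran from 1 to 2. Of the 295 genes, 3, 154, 114 and 51 were kept without strain 1, 2, 3 and 4, and 256 with the block.

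The +1 shift was 4.01 bp with the call nearest the gene start and 4.04 bp with no minimum support (exact p = 0.0571 each). The difference in calls was 821 with calls of score 0.4 or more. Spacing differed by -2.5 bp with a narrower range of distances, -2.62 bp with calls of score 0.4 or more and -4.11 bp as a mean (exact p = 0.0286 each), and by -1 bp between well-positioned neighbours (exact p = 0.229) and -1.25 bp between non-overlapping calls (exact p = 0.143). The change in phased minus antiphased score was 0.00269 with a 160 bp repeat. Calls of score 0.4 or more gave 304 gained and lost nucleosomes. Assignment within 30 bp gave 1043 shifted dyads. The changed genes numbered 503 on centred scores, 188 with at least 6 calls (fewer genes tested) and 595 with the height component. Of the 2 list calls, 0 held with an estimated correlation. With fry 1 list was called, meiosis and sporulation, and neither of the 2 held (adjusted p = 0.0613 each). The 1 list called was ribosomal proteins with the width component, the median over calls and centred scores, and glycolysis with the height component (camera adjusted p = 0.0395). Calls of score 0.4 or more also gave 2 list calls, with meiosis and sporulation (0.00938) in place of glycolysis (0.163).

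With the labelled carrier the displacement of the inserted genes was 1.55 bp with calls of score 0.4 or more. With the stepped library as carrier the untreated difference was -0.0238 in score and 5.26 bp in displacement, or -0.0243 and 6.68 bp with calls of score 0.4 or more, and under phenanthroline 0.00417 and 1.51 bp. Subtracting the mean of all genes leaves these tests as they are, since each strain carries the same number of genes, and was not run for displacement.

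Among named genes outside the 20 largest, the difference changed sign with the width component alone in CAM1 (-0.0506), CDC19 (-0.00210), FBP1 (-0.0118), ICL1 (-0.0122), SQT1 (-0.0123), TEF4 (-0.0260) and YDJ1 (-0.00260). With calls of score 0.4 or more it did in TEF4 (-0.0182), CLB1 (-0.0490), KIN3 (-0.0405) and TSA1 (0.0542). It was -0.0249 for CLB1 with the median over calls and 0.00350 for HTA2 on centred scores. Without 1 strain label CAM1 ran from -0.0160 to 0.0401, HTA2 from -0.0718 to 0.0269 and HTB2 from -0.0738 to 0.00343. The 20 largest kept their direction in all settings, past the threshold in 181 fits and not in 41, but not their size: it was smaller by over 1.5 times in 6 of 17 genes with calls of score 0.4 or more, 12 of 20 with the width component and 2 of 20 with the median over calls, and larger by as much in 7 with the height component and 2 with the median. The unknown depth of single libraries limits any statement on the height score.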

Other observations

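Chosen after the result was seen were the tests of the shorter dyad distance, of digestion, of the other splits of the libraries and of the inserted genes in the stepped libraries, and the label of the paralog test was made stricter after its first value was seen. The tests on matched lists, on paralogs and of the distance from +1 to last without overlapping calls were chosen before their results.

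Calls on mitochondrial DNA numbered 1, 27, 45 and 138 in the untreated libraries labelled strain 1 to 4 and 2, 2, 0 and 0 in the treated ones. The share of calls classed as uncertain rose from 0.422% ± 0.0708 to 0.679% ± 0.0533 (SD, n = 4, exact p = 0.0286, adjusted p = 0.0429, 0.125 with the strain block), and the mean width score was 0.624 and the mean height score 0.695 without and 0.608 and 0.682 with phenanthroline. By position, the score difference was -0.0452 at the -1 nucleosome and -0.0288 at the +1, each with an exact p of 0.0286 and an adjusted p of 0.114 over 8 positions, lower in 4 of 4 strain labels.

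For the +1 shift 4 gene groups were called with camera's preset correlation, and none of the 4 held with an estimated correlation. Under phenanthroline the +1 of mitochondrial ribosome genes lay farther downstream in 18 of 41 members and upstream in 0 (median 5.25 bp against 3.5 bp over all genes, camera adjusted p = 0.0120, 0.863 with an estimated correlation). That of chaperone genes lay farther upstream in 4 of 17 members and downstream in 1 (median -1.5 bp, camera adjusted p = 0.000916, 0.105 with an estimated correlation). Ribosome biogenesis genes had a median of 1 bp (camera adjusted p = 0.0329, 0.863 with an estimated correlation), with 6 of 67 members farther downstream and 3 upstream. Meiosis genes had a median of -0.5 bp (camera adjusted p = 0.0316, 0.382 with an estimated correlation), with limma calling 0 of 15 members in either direction (at an unadjusted p below 0.05, 2 downstream and 1 upstream). Ribosome biogenesis lost its call without the libraries labelled strain 2 (0.293), and meiosis without those labelled strain 1 (0.139) or 2 (0.113).

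Neighbouring dyads lay closer together under phenanthroline, and so did the +1 and last nucleosome of a gene. Whether the larger share of overlapping calls accounts for the shorter median distance cannot be told apart from closer nucleosomes. Among calls that overlap no other call the difference was -1.25 bp (exact p = 0.143) in place of -4.25 bp, but that selection removes every distance shorter than a call, 33.8% of distances in untreated and 42.0% in treated libraries. The shorter distance from +1 to last is not accounted for by such calls alone, because without them it was still -9.49 bp (exact p = 0.0286, 328 genes). A difference in digestion between the groups may contribute and cannot be told apart from the treatment, because the calls carry no fragment lengths and the lower score of the -1 nucleosome (-0.0452) would follow from either. An effect of the treatment itself on spacing stays open and was not tested apart from these.

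Ribosomal protein genes had a higher gene-body score under phenanthroline, from a lower level than other genes. The list median of 0.0246 stood at percentile 100 of 10000 random lists matched on the mean score over both treatments. The middle 95 percent of those lists ran from -0.0147 to 0.00732. A return of low-scoring genes towards the mean stays open. Matching on both treatments, and not on the starting score, takes such a return out of the random lists. Reads shared between paralogs would raise the genes with a second copy most, but the 11 single-copy genes had a median of 0.0437 and the 81 others 0.0201 (permutation p = 0.349). An effect of the treatment on these genes stays open and its mechanism was not tested. The list was not called with an estimated correlation (adjusted p = 0.206) or with the height score alone (adjusted p = 0.442).

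For each count of the treatment comparison the real split alone, 1 of 35 splits, gave a count as large. That is the smallest share that splits ignoring the strain numbers allow, so chance is unlikely over them but not excluded. The real counts and the highest of the other splits were 295 and 1 for gene-body scores, 4067 and 0 for nucleosome scores, 544 and 25 for shifted dyads, 153 and 45 for gained and lost nucleosomes, 1112 and 10 for depleted region widths and 845 and 6 for +1 positions. Of the other splits, 7 also part every pair of libraries of 1 strain number, and their highest counts were 0, 0, 7, 35, 2 and 0 in the same order. These 8 splits, the real one included, allow no share below 0.125, so chance is not excluded within the pairing, although the real count was the highest. Under the strain block limma called 0 shifted dyads, 65 widths and 8 +1 positions.

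If the libraries with the step are the true carriers, the 8 inserted genes give a test of whether gene length sets the regularity of the array. Under that assumption the score would fall in the 6 genes that 81 bp more make antiphased and rise in the other 2, DGK1 and BSP1. The mean difference signed by that rule was 0.0937 in untreated libraries, with 7 of 8 genes in the predicted direction. It was the highest value of the 24 assignments (highest other 0.0631) and was found after the differences had been seen. The predicted phases, and so the signs, depend on the repeat length. The 160 bp repeat, with which the change in phased minus antiphased score was 0.00269, was not tried for the inserted genes. The signed result therefore holds for the repeat length used only. The rule counts all 8 genes alike, although the predicted changes differ in size. With 81 bp more, the distance off a whole multiple would go from 46 to 35 bp in DGK1. It would go from 29 to 52 bp in SLM3 and from 31 to 53 bp in PAN5. The other genes would change more, as from 6 to 78 bp in TRP4 and UBX5. The largest score difference at least 150 bp from the sites thus came from DGK1, the gene with the smallest predicted change. At least 150 bp from the sites, the largest differences in the stepped untreated libraries were 0.268 in DGK1, -0.198 in UBX5, -0.173 in TRP4, -0.131 in CKB2 and 0.113 in PAN5, the last against its predicted direction. Under phenanthroline the signed mean of these calls was 0.00385, reached by 13 of the 24 assignments. With all calls in the gene it was 0.118 in untreated libraries (highest other 0.0790) and 0.0451 under phenanthroline (highest other 0.0343), the highest of the 24 assignments in both. Whether the stepped libraries stood apart more without phenanthroline was tested on the unsigned differences, which were larger by 0.0487 in untreated libraries, a value that 6 of the 24 assignments reached (highest other 0.0564), so a dependence on treatment was not shown.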
